A study of Mus musculus with 6 samples.

How the data were processed

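Reverse-transcription stops at RNA G-quadruplex sites (rG4s, 4-stranded structures formed by runs of guanines) were measured in a mouse embryonic stem cell line on days 0, 3 and 7 of embryoid body differentiation, with 2 replicates per day. The labels describe a clonal line from a cross of 129S1/CastEiJ with 129S1 that carries the TsixTST allele beside a normal one, grown on inactivated feeder cells and freed of them before differentiation without leukemia inhibitory factor. Embryoid bodies were kept in suspension until day 3 and grown attached after it. Cells were treated with dimethyl sulfate (DMS), which methylates guanines at a position that is free in an unfolded motif and protected in a folded one. Chromatin-bound polyadenylated RNA was then broken into short fragments and reverse transcribed with K+, which lets unmodified G-quadruplexes fold and stop the enzyme, or with Li+, which does not stabilise them. A stop in K+ above the level in Li+ therefore marks a motif that was protected from DMS in the cell. Each day 7 sample also carries a second table that its name describes as in vitro. The labels do not describe that preparation, so its identity rests on the name and on the series' design text.

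Per the submitters' processing notes, cutadapt, STAR and SAMtools were used upstream, with versions not stated, and the builds were GRCm38.p6 and mm10. The settings of the alignment, the treatment of reads with several matches and the use of strand are not given in the sources used here. Per the file headers, the deposited tables give for each site the coverage and the number of stops as whole-number read counts, in K+ and in Li+, without normalisation, together with the gene, the structural class, the transcript region and the coordinates of the motif and of the stop. Motif coordinates below are 1-based on that build, as deposited. All 8 tables list the same 5538 sites in 2643 gene entries, and 2670 of 2735 gene symbols were found in the reference table, 8 of them only as a synonym. In both in vitro tables every one of the 5538 sites had a higher stop share in K+ than in Li+, with a lowest ratio of 1.10, so the sites were chosen on those tables or on data like them. No column lists a coverage between 1 and 5, so a listed 0 stands for at most 5 reads, and 2 sites of Xist carried no value in day 0 replicate 1, which was taken as 0 in the tests. A group listed at 0 throughout was set to that floor, 5 reads per library for 1 cation and 10 for the sum of both, and folds against it are given as "at least". The listed coverage in cells ran from 413278 to 4212056 reads per library and cation, of which 13 sites in ribosomal RNA and mitochondrial RNA held 63.5% to 83.8%.

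K+ stop counts were compared between days with limma-voom (limma 3.58.1 in R 4.3.3) on all 6 in-cell libraries in 1 fit without covariates, after scaling by trimmed mean of M values. Sites entered with 10 stops at the median library size in at least 2 libraries and 15 in all. Each record runs over 2 lines of the table, and for this reason of record keeping limma-voom took the place of the quasi-likelihood count test chosen at first. The values themselves are counts and would have allowed that test. The stop share, that is stops over coverage, was tested as its log2 odds with a pseudocount of 0.5 in limma, weighted by a beta-binomial variance, at sites with 20 or more reads in every library. The same model with both cations gave the K+ against Li+ odds within a day and the change of those odds between days. Reads of both cations were summed at the site with the most reads of each gene and tested with limma-voom as a measure of the amount of RNA. The in vitro tables were set against the day 7 tables by the same steps. In each test, calls have a Benjamini-Hochberg adjusted p under 0.05. Fisher's exact test, two-sided, was applied to K+ and Li+ counts in each replicate. Means per library were compared by exact permutation tests, two-sided, which cannot go below 0.333 with 2 against 2. Intervals are exact Clopper-Pearson intervals and, like the floor for a listed 0, cover counting error only. The replicates are not stated to come from separate cultures, so p-values measure the spread between these samples. A single library left alone in its group was assumed to vary like the others.

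A quasi-binomial model was the first share test run on the real tables, and its counts were seen. It was replaced because it made too many false calls in simulated data. In a simulation of day 7 against day 0 at 945 sites it made 28 false calls among 173 (16.2%), against 1 among 118 for the weighted odds, which recovered 23% of 4-fold and 94% of 16-fold changes. For K+ against Li+ at 838 sites the false calls were 58 among 223 (26%) and 4 among 149. For the in vitro comparison at 3487 sites they were 9 among 163 (5.52%) and 6 among 189. Shares were simulated from a beta-binomial distribution, the form that the weights assume, which favours the test that was kept. Each site and library was drawn separately, with no shift common to a library. In the real data the median K+ share was 5.41% and 3.03% in the day 3 samples. The simulated false calls do not cover an error of that kind. For K+ stop counts at 327 sites, 53.7% of 4-fold and 97.5% of 16-fold changes were recovered, with 6 false calls among 67. Fisher's test in both replicates was looked at on the real tables before it was simulated. It then made 19 false calls among 118 (16.1%) for K+ against Li+ at 3036 sites, so its sites are given as a description.

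The grouping, the comparisons of K+ stops and stop shares, the in vitro comparison of stops, the list and class tests, the rule for naming genes and most alternatives were fixed before the data were examined. The K+ against Li+ odds, coverage per gene, the in vitro comparison of shares, Fisher's test in both replicates and an exchange of the cation columns of day 0 replicate 2 were added after the data were seen. Named sites are, per comparison, up to 8 with the largest increase and 8 with the largest decrease among calls with a mean of 20 or more stops and groups that do not overlap, up to 2 members per direction of each list, the Xist and Tsix sites and the 5 sites with the highest counts. The 16 lists were tested with camera at a preset correlation of 0.01 and again with an estimated one: pluripotency, formative and primitive streak, neural, mesoderm with heart and vessel, endoderm, feeder fibroblast, X-inactivation locus, Xist partners and silencing, Polycomb, Polycomb-target developmental, imprinted, nuclear long noncoding RNA, rG4 helicases and binders, chromatin and transcription, stress and immediate early, and translation and housekeeping. Alternatives covered the scaling, the filters, the coverage minimum, the fit of single pairs of days, sums per gene, each library left out and the removal of ribosomal and mitochondrial sites. Positions within a motif were not analysed here, since the tables give 1 stop mark per site. Tables were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.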

Results

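Stops at rG4 sites were measured in chromatin-bound polyadenylated RNA of differentiating mouse embryonic stem cells on day 0, day 3 and day 7, with 2 samples per day and 1 K+ and 1 Li+ library per sample. Outside ribosomal and mitochondrial RNA the K+ libraries held 479752 and 143603 listed reads on day 0, 87473 and 187292 on day 3, and 831274 and 440604 on day 7, with 21400, 7581, 8414, 9173, 48543 and 19258 stops. The Li+ libraries held 299497, 152113, 423817, 94677, 1536411 and 342751 listed reads in the same order. Of the 5538 sites, 867 were canonical motifs with short loops, 2775 lay in 3′ untranslated regions, 1342 in coding sequence, 639 in 5′ untranslated regions and 236 in noncoding transcripts, and 161 lay on chromosome X. Between the replicates of a day, log2 K+ stop counts correlated across sites with Pearson's r of 0.89 on day 0, 0.85 on day 3 and 0.88 on day 7, and K+ stop shares with Spearman's rho of 0.36, 0.49 and 0.73. Between samples of different days r ran from 0.57 to 0.88 and rho from 0.24 to 0.57, so both overlapped the values within days. Sites are not independent replicates.

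The comparison of day 7 with day 0 asked which K+ stop counts at rG4 sites changed in the course of differentiation. These counts are not corrected for stops in Li+. H19, the imprinted noncoding RNA of the Igf2 locus, had no stop in either day 0 library and 250 and 44 on day 7 at a motif on chromosome 7 from 142576936 to 142576995, a rise of at least 5.82-fold (adjusted p = 0.00143). Xist, the RNA that coats the inactive X chromosome, rose at all 3 sites tested, 1 of which carried no value in day 0 replicate 1 and was taken as 0 there. A canonical Xist motif on chromosome X from 103460424 to 103460446 went from 0 and 0 stops to 91 and 41, at least 3.21-fold (adjusted p = 0.0033). At the motif from 103461852 to 103461877 Xist had 67 and 22 stops on day 7, at least 2.01-fold above day 0 (adjusted p = 0.00143). The K+ share there was 11.9% and 6.49% on day 7, against 9.77% and 8.01% in Li+, so these stops were near the Li+ level. Tsix overlaps Xist on the opposite strand, and the use of strand in counting is not given in the sources used here.

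Ccn1, a matricellular protein, rose at least 2.61-fold in its 3′ untranslated region (89 and 28 stops on day 7). Flnc, the muscle form of filamin, rose at least 1.74-fold, and Jun, an immediate early transcription factor, at least 1.65-fold. Fgf8, a growth factor of the primitive streak, rose at least 1.31-fold, with 39 and 16 stops on day 7 and none on day 0. Peg3, a paternally expressed zinc finger gene, had 1 and 0 stops on day 0 and 94 and 40 on day 7 (adjusted p = 0.00143). Malat1, a nuclear speckle RNA, rose by 3.42 ± 0.66 (log2, SE), from 50.8 ± 13.2 to 598 ± 170 CPM (SD, n = 2; stops after scaling). Ddit4, an inhibitor of mTORC1 induced by stress, rose by 2.32 ± 0.51, from 84.5 ± 6.14 to 444 ± 79.4 CPM (SD, n = 2), at a canonical motif of its 3′ untranslated region on chromosome 10 from 59949823 to 59949845. Peg10, an imprinted gene derived from a retrotransposon, rose by 3.19 ± 0.62, and Laptm4a, a lysosomal membrane protein, by 2.98 ± 0.68.

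Among the sites that fell, Pou5f1, which encodes the pluripotency factor Oct4, changed by -2.72 ± 0.58 (log2, SE; adjusted p = 0.0119), from 1852 ± 180 to 314 ± 247 CPM (SD, n = 2), at a motif on chromosome 17 from 35506093 to 35506152 at the start of its coding sequence. Mybl2, a cell cycle transcription factor, changed by -2.93 ± 0.73, with 12 and 2 stops on day 0 and 2 and 2 on day 7. The translation factor Eif5a changed by -3.32 ± 0.71, the ribosomal protein gene Rps15 by -2.07 ± 0.42, the cytochrome oxidase subunit gene Cox8a by -3.18 ± 0.68, the glycolytic enzyme gene Pkm by -2.08 ± 0.56, the tubulin gene Tuba1b by -2.21 ± 0.59 and the nucleolar protein gene Ncl by -1.51 ± 0.39. Eif5a, Rps15 and Tuba1b have close copies elsewhere in the genome, and how shared reads were counted is not given in the sources used here, so their values are uncertain. Ankrd60, an ankyrin repeat gene, changed by -4.71 ± 1.18, and Pnck, a calmodulin-dependent kinase gene, by -2.33 ± 0.63.

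In all, 53 of 327 sites changed between day 0 and day 7, 33 up and 20 down (limma-voom, 97 sites at an unadjusted p under 0.05). The list of sites was chosen on the in vitro data, which belong to the day 7 samples, or on data like them. Sites of RNA lost by day 7 may be missing from it, which would favour rises, and this was not tested. The K+ coverage moved in the direction of the stops at 33 of the 33 sites that rose and 19 of the 20 that fell. Stops are part of the coverage, and a site with coverage listed at 0 on day 0 can only rise in both. The shared direction is therefore partly built in. The split depended on the scaling: with total stop counts alone the median log2 change over all sites was 1.26 in place of 0.16, and 93 sites passed, 89 up and 4 down. With no filter on low counts 154 sites passed, 132 up and 22 down, and with day 0 and day 7 fitted alone 90 passed, 62 up and 28 down. Without day 0 replicate 2 only 21 sites passed (20 up), without day 7 replicate 1 30 (26 up), without day 0 replicate 1 41 (38 up) and without day 7 replicate 2 69 (35 up).

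The named H19, Ccn1, Peg3, Flnc and Jun sites passed with any 1 library left out, as did the Xist site from 103461852. Without day 0 replicate 1 the Xist site from 103460424 missed the threshold (adjusted p = 0.0845, over its alternatives 1.91e-09 to 0.0845), as did Fgf8 (0.0874, 9.32e-07 to 0.0874), Malat1 (0.0773, 4.32e-06 to 0.103), and Ddit4 (0.113, 0.000253 to 0.113). So did Pou5f1 (0.0773, 5.78e-05 to 0.164), Mybl2 (0.0788, 0.00795 to 0.252), Eif5a (0.0845, 7.56e-05 to 0.142), Cox8a (0.166, 0.000251 to 0.166), Ankrd60 (0.144, 3.18e-10 to 0.292), Pnck (0.0908, 0.000814 to 0.277), Pkm (0.172, 0.00365 to 0.299), Tuba1b (0.175, 0.00287 to 0.227) and Ncl (0.107, 0.0221 to 0.621). Without day 0 replicate 2 the adjusted p was 0.164 for Pou5f1, 0.0704 for Mybl2, 0.142 for Eif5a, 0.103 for Malat1, 0.0753 for Ddit4, 0.292 for Ankrd60, 0.277 for Pnck, 0.195 for Pkm, 0.2 for Tuba1b and 0.118 for Ncl. It was also 0.0753 for Rps15 (0.00019 to 0.187), 0.0818 for Peg10 (1.83e-05 to 0.0818) and 0.206 for Laptm4a (4.97e-05 to 0.206). Without day 7 replicate 1 it was 0.252 for Mybl2, 0.0792 for Cox8a, 0.295 for Pkm, 0.185 for Tuba1b, 0.171 for Ncl and 0.185 for Pnck. With total stop counts alone it was 0.12 for Mybl2, 0.187 for Rps15, 0.299 for Pkm, 0.227 for Tuba1b, 0.621 for Ncl and 0.0557 for Pnck, and with no filter 0.115 for Mybl2, 0.0591 for Rps15, 0.184 for Pkm, 0.143 for Tuba1b and 0.444 for Ncl. With the cation columns of day 0 replicate 2 exchanged it was 0.0799 for Pou5f1, 0.209 for Mybl2, 0.11 for Laptm4a, 0.0799 for Tuba1b, 0.11 for Ncl and 0.0624 for Pnck. Pnck also missed the threshold without ribosomal and mitochondrial sites (0.0716), and Ncl with stops summed per gene (0.121).

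Day 3 was set against day 0 for the early phase of differentiation. Ddit4 rose by 2.76 ± 0.49 (log2, SE; adjusted p = 0.0362), from 84.5 ± 6.14 to 630 ± 198 CPM (SD, n = 2). Wnk1, a kinase of ion transport, was the other of the 2 sites that passed. It lies outside the naming rule, was named after its values were seen, and had 2 and 0 stops on day 0 and 11 and 12 on day 3 at a canonical motif of its 3′ untranslated region (adjusted p = 0.0362). Cdh3, the gene of P-cadherin, had 1 and 0 stops on day 0 and 6 and 8 on day 3 (adjusted p = 0.0742) and did not pass. Neither did the lactate transporter gene Slc16a3 (4 and 0 against 11 and 10, adjusted p = 0.0985) or Tmsb4x (31 and 12 against 0 and 4, adjusted p = 0.0985). Of 327 sites, 2 rose and 0 fell (limma-voom, 45 at an unadjusted p under 0.05). With total stop counts alone the median change was 1.08 in place of 0.11 and 43 passed, 41 of them up, with no filter 14 passed, 4 up and 10 down, and summed per gene 6 passed, 4 up and 2 down. Ddit4 missed the threshold with median-ratio factors (adjusted p = 0.0538), without day 0 replicate 1 (0.138), day 0 replicate 2 (0.203) or day 3 replicate 2 (0.0674), and with the cation columns of day 0 replicate 2 exchanged (0.129). Its adjusted p ran from 0.000573 to 0.203 over the alternatives. The count was 0 with median-ratio factors (48 at an unadjusted p under 0.05). The median change over all sites was 0.09 without day 0 replicate 2 and 0.08 without day 3 replicate 1, in place of 0.11. It was 0.21 without day 3 replicate 2 and -0.04 without day 0 replicate 1.

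From day 3 to day 7, Ccn1 went from 0 and 0 stops to 91 and 37 at a motif on chromosome 3 from 145647592 to 145647612, at least 3.35-fold higher (adjusted p = 0.00177). H19 rose at least 2.93-fold at a motif from 142576933 to 142576992 and Peg3 at least 1.96-fold at a motif from 6704461 to 6704520, both on chromosome 7. These 3 sites are other sites than those given above for the same genes. Xist rose at least 2.21-fold at the site from 103461852, Flnc at least 1.92-fold and Jun at least 1.81-fold. Pou5f1 fell by 2.33 ± 0.55 on the log2 scale (adjusted p = 0.0396) and Mybl2 fell by 3.62 ± 0.70 (adjusted p = 0.0141). Of 327 sites, 18 rose and 3 fell (limma-voom, 58 at an unadjusted p under 0.05). With no filter 134 passed, 123 up and 11 down, summed per gene 39 passed, 25 up and 14 down, and with total stop counts alone the median change was 0.09 in place of -0.05. Without day 3 replicate 1 only 14 sites passed. The Xist site from 103460424 rose by 3.42 ± 0.88 (adjusted p = 0.0494) and missed the threshold with median-ratio factors (0.0711), with day 3 and day 7 fitted alone (0.253), without day 3 replicate 1 (0.37) and without day 7 replicate 2 (0.054), over alternatives from 0.00092 to 0.37. Pou5f1 missed the threshold with median-ratio factors (adjusted p = 0.0605), with day 3 and day 7 fitted alone (0.135), without day 3 replicate 1 (0.0843), day 3 replicate 2 (0.1) or day 7 replicate 1 (0.121), and with the cation columns exchanged (0.0584), over alternatives from 0.000364 to 0.135. Mybl2 did so with day 3 and day 7 fitted alone (0.0686) and without day 7 replicate 1 (0.195), over alternatives from 0.00265 to 0.195.

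The gene lists were tested as groups. With an estimated correlation camera takes its degrees of freedom from the 6 libraries instead of the sites, which by itself raises p. Many sites of a list lay in the same gene. Of 14 sites in 4 imprinted genes, 13 rose from day 0 to day 7, 8 in H19, 3 in Peg10 and 2 in Peg3 (14 adjusted over the list alone; camera adjusted p = 3.99e-12, and adjusted p = 0.153 with an estimated correlation). Of 24 sites in 4 nuclear long noncoding RNAs, 12 rose, 8 in H19, 3 in Xist and 1 in Malat1 (19 adjusted over the list alone; camera adjusted p = 3.99e-12, and adjusted p = 0.153 with an estimated correlation). H19 and Xist each belong to this list and another. All 3 sites of the X-inactivation locus, each in Xist, rose (3 adjusted over the list alone). Of 9 sites of 3 stress and immediate early genes 4 rose, 3 in Ddit4 and 1 in Jun (5 adjusted over the list alone; camera adjusted p = 0.0041, and adjusted p = 0.153 with an estimated correlation), and the 1 site of a formative and primitive streak gene, Fgf8, rose. Of 6 sites of 5 pluripotency genes 3 fell, 2 in Pou5f1 and 1 in Mybl2 (3 adjusted over the list alone; camera adjusted p = 0.0357, and adjusted p = 0.215 with an estimated correlation). That list missed the threshold without day 0 replicate 1 (adjusted p = 0.0871) and without day 7 replicate 1 (0.0689). Of 29 sites of translation and housekeeping genes 4 fell (4 adjusted over the list alone; camera adjusted p = 0.000646, and adjusted p = 0.164 with an estimated correlation). Of 29 sites of rG4 helicases and binders 1 fell (0 adjusted over the list alone; camera adjusted p = 0.0975), and no site of the 2 tested in each of the chromatin and transcription, Polycomb, and Xist partners and silencing lists passed. In the test of day 3 against day 0, camera placed nuclear long noncoding RNAs (adjusted p = 9.44e-06), stress genes (0.000165) and imprinted genes (0.00183) higher and translation genes (0.000862) lower, while 1 stress site passed by itself. With an estimated correlation these adjusted p were 0.215, 0.153, 0.283 and 0.164. Without day 0 replicate 1 the nuclear noncoding RNAs (adjusted p = 0.0871) and the imprinted genes (0.0981) missed the threshold there, and with stops summed per gene the stress genes did (0.367). From day 3 to day 7 it placed imprinted genes (5.57e-12) and nuclear noncoding RNAs (2.84e-07) higher and pluripotency genes (0.000574) lower, with adjusted p of 0.153, 0.215 and 0.153 with an estimated correlation, and with stops summed per gene the nuclear noncoding RNAs missed the threshold (0.367). With 12 calls at the preset correlation there were 0 with an estimated one.

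The number of reads over a site, K+ and Li+ together, served as a measure of the amount of RNA. From day 0 to day 7, Xist rose at least 11.5-fold, from 0 and 0 to 515 and 234 reads at the motif from 103461239 to 103461253, shared with Gm27733 (adjusted p = 0.000974). At the Xist motif from 103460407 to 103460446, with 1691 and 686 reads on day 7, day 0 replicate 2 was listed at 0. Replicate 1 carried no value there and was taken as 0 (adjusted p = 0.000855, and 0.00157 without it). H19 went from 44 and 0 reads to 25662 and 3827 (adjusted p = 0.00585). Car4, a membrane carbonic anhydrase, rose at least 41.2-fold, Fgf8 at least 32.5-fold and Jun at least 30.2-fold. The epithelial keratin genes Krt8 and Krt18 rose at least 22.0-fold and 27.2-fold, and Dbn1, which encodes an actin-binding protein of neurons, at least 16.8-fold. The neuronal imprinted gene Nnat rose at least 11.2-fold, the neural transcription factor gene Sox11 at least 6.90-fold, the collagen gene Col1a1 at least 1.55-fold and T, which encodes the mesoderm factor brachyury, at least 1.10-fold. Zfp57, which maintains imprints, changed by -3.10 ± 0.33 (log2, SE), from 624 ± 74.5 to 76.9 ± 26.4 CPM (SD, n = 2). Pou5f1 changed by -2.74 ± 0.43, from 1782 ± 38.5 to 304 ± 194, Mybl2 by -3.95 ± 0.52, and Epop, a Polycomb-associated elongin partner, by -2.49 ± 0.40.

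**Figure D1:**
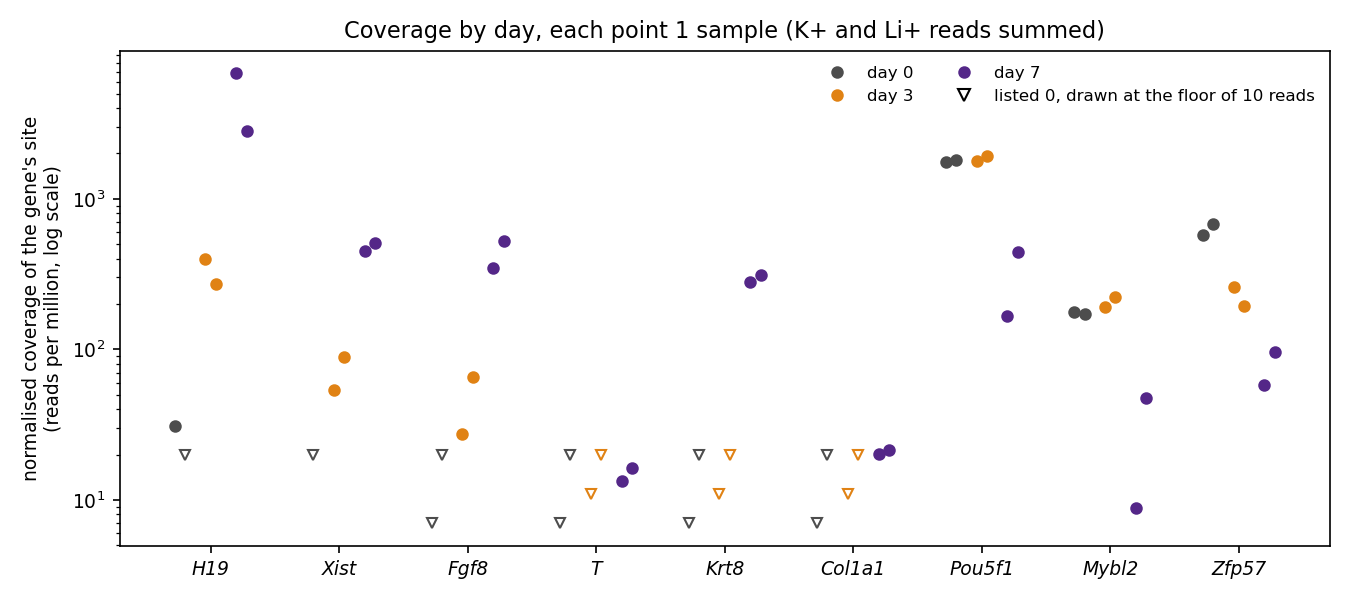
Normalised coverage (CPM, log scale) of the site of 9 genes in each of the 6 samples, with open triangles at the floor of 10 reads for samples listed at 0. No value was given for Xist in day 0 replicate 1. H19, Xist, Fgf8 and Krt8 lie higher on day 7 than on day 0, and Pou5f1, Mybl2 and Zfp57 lower.

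In all, 439 of 2389 genes changed between day 0 and day 7, 364 up and 75 down (limma-voom), 302 between day 3 and day 7, 257 up and 45 down, and 2 between day 0 and day 3, Car4 (at least 10.6-fold, adjusted p = 0.0284) and Xist (49 and 45 reads on day 3 at the motif from 103460407, adjusted p = 0.0284, and 0.00591 without day 0 replicate 1, which carried no value). The other Xist site did not pass (0.402). From day 3 to day 7 Krt19, a further keratin gene, rose at least 9.47-fold and Egr1, an immediate early factor, at least 2.29-fold, while the pluripotency factor gene Esrrb changed by -2.86 ± 0.52 and the DNA methyltransferase gene Dnmt3a by -1.77 ± 0.36. The choice of sites on the in vitro data of the day 7 samples, or on data like them, may favour rises, since RNA lost by day 7 may be missing. The K+ libraries listed 1042 and 2848 sites at 0 on day 0 and 168 and 515 on day 7. An effect of that choice on the split was not tested. Many of the rises began at a listed 0: among the 1368 genes listed above 0 in all 6 samples, 125 changed from day 0 to day 7, 71 up and 54 down, 76 from day 3 to day 7, 38 each way, and 5 from day 0 to day 3. With total coverage as the scale the day 7 against day 0 split was 429 up and 17 down, and the median change was 1.01 in place of 0.57, against 0.28 and 0.16 for day 3 against day 0 and 0.65 and 0.33 for day 7 against day 3. With the K+ libraries alone 25 genes passed from day 0 to day 3, 2 up and 23 down. For day 7 against day 0, leaving out day 0 replicate 1 gave 1064 genes, day 0 replicate 2 234, day 7 replicate 1 113 and day 7 replicate 2 277. Day 7 against day 3 gave 585 without day 3 replicate 1, 0 without day 3 replicate 2 (limma-voom, 356 at an unadjusted p under 0.05) and 91 without day 7 replicate 1. For day 3 against day 0 the median change was 0.26 without day 0 replicate 1 and 0.03 without day 3 replicate 1, in place of 0.16. It was -0.11 without day 0 replicate 2 and 0.15 without day 3 replicate 2, so its direction was not stable. Car4 and Xist on day 3 both missed the threshold without day 0 replicate 2 (adjusted p = 0.0782 each) and without day 3 replicate 2 (0.174 and 0.305). With the K+ libraries alone Car4 did not pass on day 3 (0.407), and with the Li+ libraries alone Xist did not (0.104), with alternatives from 0.00591 to 0.407 for Car4 and from 0.00591 to 0.305 for Xist. From day 0 to day 7 T missed it without day 7 replicate 1 (0.0929), and Pou5f1 without day 0 replicate 2 (0.0506, 0.00179 to 0.0506). From day 3 to day 7 every call ended without day 3 replicate 2, with adjusted p of 0.0627 for Krt19, 0.0628 for Egr1, 0.0627 for Esrrb and 0.11 for Dnmt3a. Esrrb also missed the threshold with the K+ libraries alone (0.2), without day 3 replicate 1 (0.084) and without day 7 replicate 1 (0.265), over alternatives from 0.00492 to 0.265. Dnmt3a did so with total coverage (0.0756), with the K+ libraries alone (0.319) and without day 7 replicate 1 (0.18), over alternatives from 0.0141 to 0.319.

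By coverage, 8 of 10 imprinted genes rose from day 0 to day 7 (8 adjusted over the list alone; camera adjusted p = 0.00172, and adjusted p = 0.473 with an estimated correlation) and 4 of 6 formative and primitive streak genes (5 adjusted over the list alone; camera adjusted p = 0.0228, and adjusted p = 0.473 with an estimated correlation). The latter list missed the threshold without day 0 replicate 1 (adjusted p = 0.099). Of 13 pluripotency genes 4 fell (2 up and 9 down adjusted over the list alone; camera adjusted p = 0.000141, and adjusted p = 0.338 with an estimated correlation). Among lists without a camera call, 2 of 4 neural genes rose, Sox11 and Sox3 (3 up and 1 down adjusted over the list alone), 5 of 14 stress genes (6), 5 of 28 chromatin and transcription genes (5) and 4 of 11 nuclear noncoding RNAs (4). Of the 3 entries of the X-inactivation locus 2 rose, both sites of Xist (2), while Rlim did not pass. Of 15 Polycomb genes 2 rose, Ring1 and Phc2, and 2 fell, Cbx7 and Epop (3 up and 3 down adjusted over the list alone). Their median change was 0.78, yet camera placed them below the rest (adjusted p = 0.551). Of 3 feeder fibroblast genes 1 rose, Col1a1, and Col5a1 and Fn1 did not pass (2 up adjusted over the list alone). Pecam1, an endothelial adhesion molecule also present in stem cells and the 1 gene of the mesoderm, heart and vessel list with a site, fell by 1.54 ± 0.39 on the log2 scale (adjusted p = 0.0333). It missed the threshold with total coverage (0.117), with the K+ libraries alone (0.0623), without day 0 replicate 2 (0.113) and without day 7 replicate 1 (0.243), over alternatives from 0.0257 to 0.243. Of 11 Xist partners 1 fell, the splicing repressor gene Ptbp1 (1 adjusted over the list alone), of 24 rG4 helicases and binders 1 rose, Hnrnph1 (1), and of 30 translation genes Eif5b rose and Eif5a fell (1 up and 1 down). The 1 endoderm gene, Sparc, did not pass over all genes (adjusted p = 0.101; 1 up adjusted over the list alone), and neither did the 1 Polycomb-target developmental gene, Cdkn2a (adjusted p = 0.869, 0 adjusted over the list alone). Sox3, Phc2, Cbx7, Ptbp1, Hnrnph1 and Eif5b each missed the threshold with at least 1 library left out, with a highest adjusted p over the alternatives of 0.25, 0.225, 0.367, 0.143, 0.125 and 0.348, and Ring1 did with coverage summed per gene (0.0667).

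From day 0 to day 3 camera placed formative genes (adjusted p = 7.84e-05), nuclear noncoding RNAs (0.000532), imprinted genes (0.00177) and the X-inactivation locus (0.00449) higher by coverage, with adjusted p of 0.473, 0.338, 0.473 and 0.473 with an estimated correlation. From day 3 to day 7 it placed imprinted genes (0.0165) higher and pluripotency genes (8.54e-05) lower, with adjusted p of 0.473 and 0.338 with an estimated correlation. Without day 0 replicate 1 the nuclear noncoding RNAs (0.165) and the X-inactivation locus (0.226) missed the threshold on day 3, without day 3 replicate 2 the imprinted genes did (0.0561), and without day 3 replicate 1 the imprinted genes did so from day 3 to day 7 (0.268). With an estimated correlation 0 of the 9 coverage calls were left.

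Stops over coverage ask whether the share of stopped reads changed, apart from the amount of RNA. The K+ share also holds stops of the kind seen in Li+, so it is not a fraction of folded motifs. At 847 sites with 20 or more reads in every column the median K+ stop share was 2.16% ± 0.284 on day 0, 4.22% ± 1.68 on day 3 and 3.47% ± 1.05 on day 7 (SD, n = 2), and the median Li+ share was 2.80% ± 0.455, 2.25% ± 0.3 and 3.07% ± 0.122. At canonical sites the K+ median was 3.08% ± 0.433, 7.57% ± 2.60 and 7.01% ± 2.20, and the Li+ median 4.88% ± 1.79, 2.76% ± 0.540 and 4.48% ± 0.624. Day 0 replicate 2, whose columns are doubted below, had 2.77% in K+ and 6.15% in Li+ there. With its columns exchanged the rise from day 0 would be smaller. No single site passed the test of the K+ share between days at 954 sites: 0 for day 3 against day 0, 0 for day 7 against day 0 and 0 for day 7 against day 3 in limma, with 81, 80 and 38 at an unadjusted p under 0.05, and 0, 0 and 0 by the quasi-binomial test, with 71, 173 and 34. Without ribosomal and mitochondrial sites the quasi-binomial test gave 2, 82 and 1. The median log2 change of the K+ odds was 0.80 from day 0 to day 3, 0.59 from day 0 to day 7 and -0.15 from day 3 to day 7. Without day 3 replicate 1 the first was 0.46 and the last 0.16, and without day 3 replicate 2 the first was 1.43 and the last -0.76, with 1 site passed. Without day 7 replicate 1 the second was 0.31 and the last -0.46, and without day 7 replicate 2 the last was 0.12. As a plain log ratio of stops to reads the second was 0.31 and the last -0.45, and with each library centred on its median they were -0.08, 0.03 and 0.13. With the cation columns of day 0 replicate 2 exchanged the first was 0.57 and the second 0.33. Among lists the 75 sites of rG4 helicases and binders had lower changes than the rest from day 0 to day 7 (camera adjusted p = 0.0405, and adjusted p = 0.958 with an estimated correlation). Their median was 0.13, above 0 but below the 0.59 of all sites, with 0 sites past the threshold, 0 adjusted over the list alone.

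**Figure D2:**
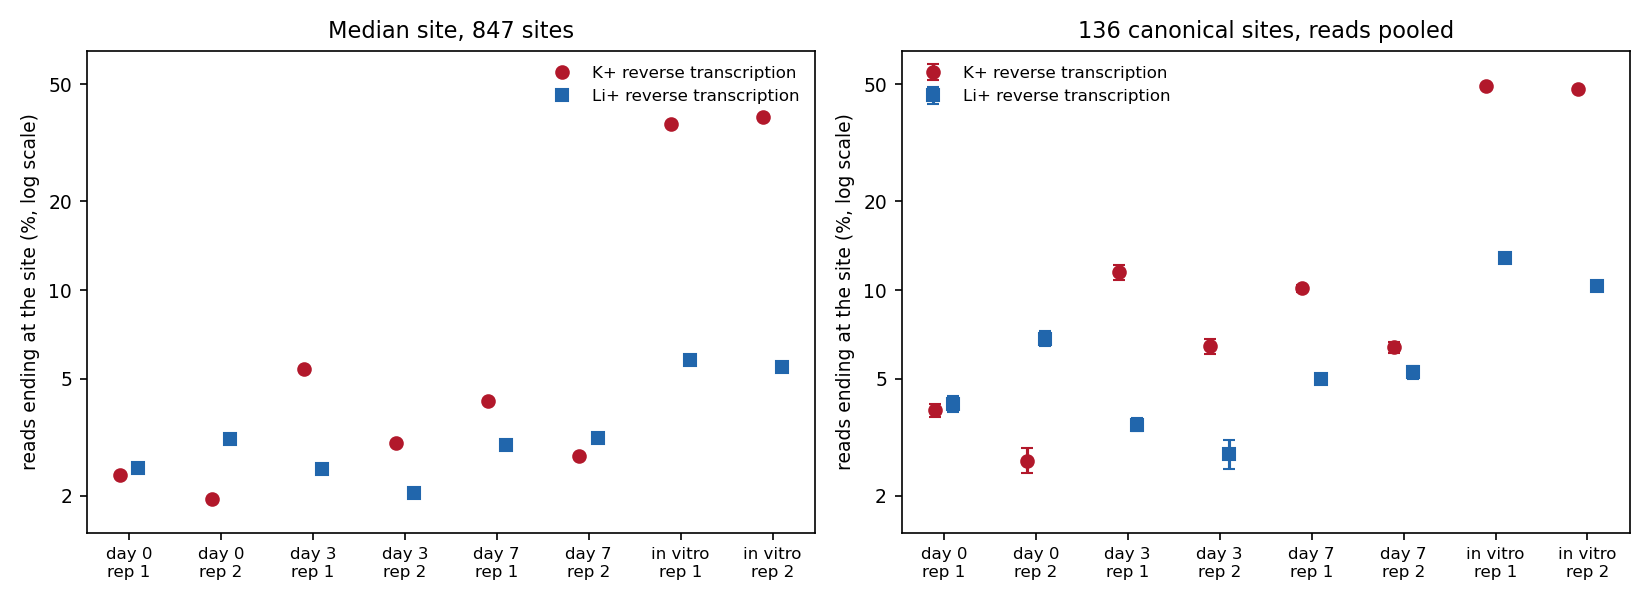
Percentage of reads that end at the site (log scale) in K+ (circles) and Li+ (squares) per library, as the median of 847 sites and pooled over 136 canonical sites with exact 95% intervals. Day 0 replicate 2 has the lower value in K+ (2.64%) and the higher in Li+ (6.84%) at canonical sites, and the in vitro tables reach 49.2% and 48.3% in K+.

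K+ was then set against Li+ within each day. On day 3, K+ odds exceeded Li+ odds at 42 of 847 sites. Pdap1, which binds PDGF, had K+ shares of 25.4% and 13.1% against 3.87% and 3.85% in Li+ at a canonical motif of its 3′ untranslated region on chromosome 5 from 145130131 to 145130157 (log2 odds ratio 2.77 ± 0.59, SE, adjusted p = 0.046). Ddit4 had 18.1% and 12.7% against 3.80% and 2.27% (2.50 ± 0.62). Prmt1, an arginine methyltransferase, had 19.2% and 8.30% against 4.14% and 3.60% (2.07 ± 0.40) on chromosome 7 from 44976835 to 44976862, and the co-chaperone gene Stip1 15.3% and 13.4% against 4.27% and 3.70% (1.97 ± 0.53). On day 0 Pdap1 had 10.0% and 3.96% in K+ against 8.11% and 14.5% in Li+, above Li+ in replicate 1 and below it in replicate 2, and Prmt1 had 4.55% and 3.63% against 5.36% and 10.9%, below Li+ in both. Ddit4 then had 13.9% and 3.33% against 4.07% and 16.2%, and Stip1 7.78% and 5.38% against 4.69% and 12.7%. On day 7 K+ lay above Li+ in both samples at each of these sites. Pdap1 had 24.8% and 16.4% against 10.2% and 7.28%, and Ddit4 13.7% and 7.49% against 7.01% and 4.65%. Prmt1 had 15.3% and 7.10% against 8.72% and 5.18%, and Stip1 21.1% and 15.1% against 7.65% and 8.66%. The higher K+ share was thus not confined to day 3 there. The K+ against Li+ odds of Pdap1 rose from day 0 to day 3 by 3.44 ± 0.73 (adjusted p = 0.0294) and those of Prmt1 by 3.09 ± 0.56 (adjusted p = 0.0274), both among 42 sites that rose and 0 that fell.

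The number of calls was 0 on day 0 (limma, 48 sites at an unadjusted p under 0.05, 1 call by the quasi-binomial test, median log2 odds ratio -0.32), 42 on day 3 (median 0.99, 7 by the quasi-binomial test) and 0 on day 7 (92 at an unadjusted p under 0.05, 34 by the quasi-binomial test, median 0.26). Between days it was 42 for day 3 against day 0 (4 by the quasi-binomial test), 0 for day 7 against day 0 (97 at an unadjusted p under 0.05, 0 by the quasi-binomial test) and 0 for day 7 against day 3 (99, and 0). Of the 42 day 3 sites 16 were canonical, against 136 of 847 tested (odds ratio 3.51, Fisher's exact test over 13 classes, adjusted p = 0.00425). That test takes sites as independent, though all the calls came from the same day 3 samples. Canonical sites also had more stops, with a median K+ share of 7.57% on day 3 against 4.22% over all sites. More stops may make a call easier, and this was not tested. Without day 0 replicate 2 1 site had lower K+ odds on day 0. The day 7 median was -0.12 without day 7 replicate 1 and 0.49 without day 7 replicate 2. The day 3 calls numbered 0 without day 3 replicate 1 (5 at an unadjusted p under 0.05, median 0.33) and 0 without day 3 replicate 2 (207, median 1.31). For day 3 against day 0 they numbered 0 without day 3 replicate 1 (23, median 0.71), 0 without day 3 replicate 2 (216, median 1.53), 32 without day 0 replicate 2 and 70 without day 0 replicate 1, and day 7 against day 0 reached 22 without day 0 replicate 1. With coverage of 50 or more, 26 sites passed on day 3 and 29 between days, and Ddit4 did not (adjusted p = 0.0516). Without day 3 replicate 1 the adjusted p on day 3 was 0.936 for Pdap1, Ddit4, Prmt1 and Stip1, and without day 3 replicate 2 it was 0.111, 0.132, 0.101 and 0.144. For the change from day 0 it was 0.831 for Pdap1 and Prmt1 without day 3 replicate 1, and 0.0712 and 0.0545 without day 3 replicate 2.

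Day 0 replicate 2 stood apart in these shares. Pooled over 136 canonical sites its K+ share was 2.64% (95% interval 2.39 to 2.91) and its Li+ share 6.84% (6.45 to 7.26), whereas the other in-cell samples had 3.91% and 4.11% (day 0 replicate 1), 11.5% and 3.50%, 6.45% and 2.77% (day 3), 10.1% and 4.99%, and 6.40% and 5.27% (day 7). Across 838 sites the mean Spearman correlation with the K+ shares of other days was 0.28 for its K+ column and 0.54 for its Li+ column. It was 0.51 and 0.48 in day 0 replicate 1, 0.44 and 0.45, and 0.46 and 0.29 on day 3, 0.47 and 0.40, and 0.48 and 0.44 on day 7, and 0.29 and 0.44, and 0.28 and 0.38 in vitro. The Li+ column was thus also the higher one in day 3 replicate 1 and in vitro. With its cation columns exchanged, 0 sites passed for day 3 against day 0 (limma, 83 at an unadjusted p under 0.05). The median change was 0.80 in place of 1.27 there and 0.13 in place of 0.65 for day 7 against day 0. Pdap1 and Prmt1 had adjusted p of 0.448 and 0.494. On day 3 the count was then 39 and on day 7 3, and the day 0 median log2 odds ratio was 0.12 in place of -0.32, with 486 of 847 sites above 0. The columns were used as deposited in every other value.

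With Fisher's exact test in each replicate, Atic, which encodes a purine synthesis enzyme, Ddit4, Lin28a, an RNA-binding protein of stem cells, and Prmt1 had a higher stop share in K+ than in Li+ in both day 3 samples, and Prrc2a, an m6A-binding protein, in both day 7 samples. Each lies at a canonical motif of a 3′ untranslated region, which was noticed after the values were seen. In Lin28a the K+ shares were 17.1% (9.66 to 27.0) and 16.1% (11.2 to 22.2) against 5.78% and 2.59% in Li+. In Prrc2a they were 16.4% and 13.7% against 1.92% and 0.704% on day 7, 18.6% against 1.01% in day 0 replicate 1, and 1.06% against 16.2% in day 0 replicate 2. On day 3 Prrc2a had 23.8% and 20.0% against 3.36% and 2.86%. The counts, ribosomal sites included, were 0 of 1282 sites on day 0, 6 of 965 on day 3 and 3 of 3045 on day 7, with 168 and 214 in replicate 1 alone on day 3 and day 7 and 7 and 6 in replicate 2 alone. Without ribosomal and mitochondrial sites 3 were left on day 3, where Atic missed the threshold in replicate 2 (adjusted p = 0.114), and 1 on day 7. Gm15564, counted here with the ribosomal and mitochondrial sites, had a higher stop share in Li+ than in K+ in both samples of day 3 and of day 7.

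The in vitro tables were set against the day 7 tables to compare stops outside the cell with stops in cells. Over 847 sites the median K+ share was 37.7% ± 1.32 in vitro and 3.47% ± 1.05 in cells (SD, n = 2; exact permutation test, p = 0.333, the smallest this design allows). The share rose at 3482 of 3497 sites and fell at 2, by a median log2 odds of 4.30 (limma), and in Li+ at 130 of 2648 sites, by a median of 0.86. At canonical sites the K+ share was 44.1% ± 1.95 in vitro and 7.01% ± 2.20 in cells. For example, Lin28a had 89.0% and 91.8% in vitro against 10.8% and 8.38% in cells. By stop counts, 668 of 4644 sites differed, 377 higher and 291 lower in vitro, after a scaling that removes most of the overall gain. Each in vitro table belongs to 1 day 7 sample, and with a replicate block 456 sites differed, 233 higher and 223 lower. With total stop counts alone the median change was 3.01 in place of 0.27 and 4059 differed, 4046 of them higher. Without day 7 replicate 1 or 2 there were 1877 and 1792, and without in vitro replicate 1 or 2 there were 308 (101 higher) and 323 (107 higher).

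Xist held 11 of the sites. Several of its motifs overlap, so a read can enter the sums below at more than 1 site, and the pooled intervals are too narrow. On day 0 all 11 sites were listed at 0 or without a value. On day 3 its K+ coverage summed to 19 and 75 reads and on day 7 to 3034 and 1725. On day 7 the pooled stop share was 8.44% (95% interval 7.47 to 9.48) in K+ and 5.37% (4.76 to 6.02) in Li+ in replicate 1, and 7.30% (6.12 to 8.63) and 7.55% (6.21 to 9.06) in replicate 2. In vitro it was 42.6% and 38.7% in K+ and 24.8% and 19.4% in Li+. Of its 2 canonical motifs the one from 103460424 to 103460446 had 51.1% (43.5 to 58.7) and 41.8% (32.0 to 52.2) in K+ against 26.9% (21.4 to 33.0) and 27.0% (16.6 to 39.7) in Li+ on day 7, and 93.9% and 97.2% in K+ in vitro. Its Li+ share in vitro was 63.3% and 67.5%. The other, from 103482042 to 103482062, had 2.90% and 16.7% in K+ against 4.61% and 6.45% in Li+ on day 7.

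**Figure D3:**
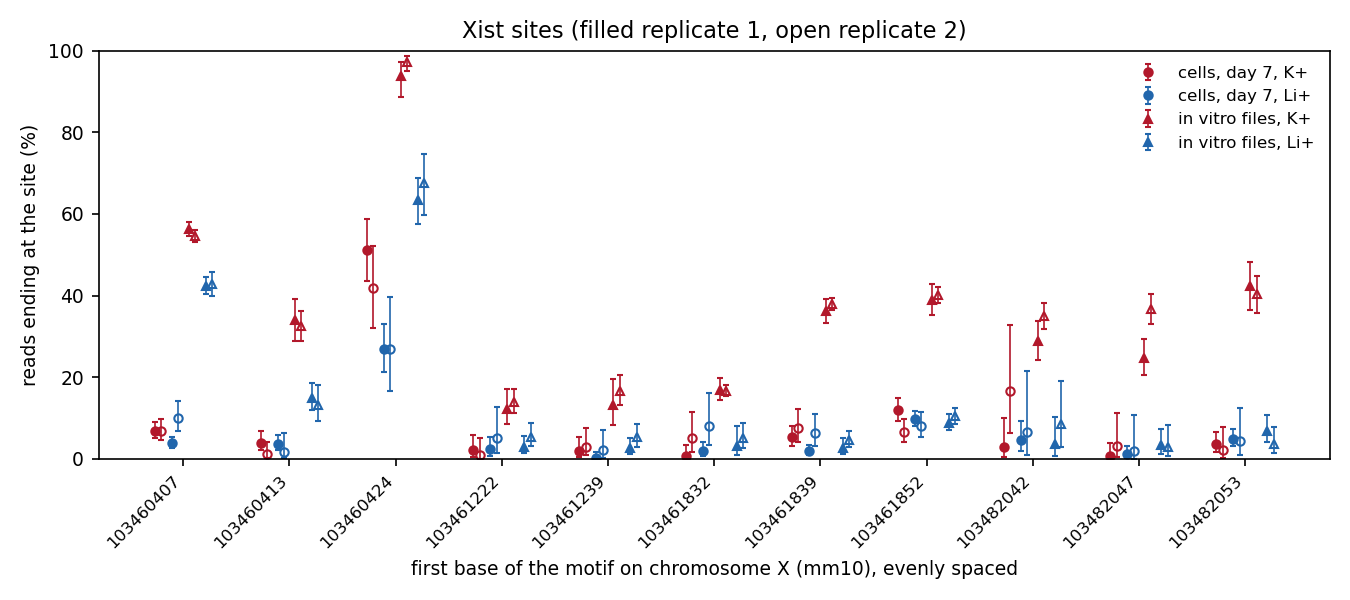
Percentage of reads that end at each of the 11 Xist sites on chromosome X (mm10) on day 7 and in vitro, in K+ and Li+, with exact 95% intervals per replicate. The motif that begins at 103460424 has 51.1% and 41.8% in K+ in cells, and the in vitro values are above the day 7 values in K+ at every site.

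Site classes were compared by their share of all K+ stops, ribosomal sites included. Canonical sites held 0.795% ± 0.318 of the stops on day 0, 2.23% ± 0.033 on day 3 and 2.57% ± 0.735 on day 7 (SD, n = 2), and sites in 3′ untranslated regions 2.61% ± 0.785, 5.43% ± 0.265 and 6.87% ± 2.33. Sites on chromosome X held 1.82% ± 0.621, 2.04% ± 0.616 and 1.28% ± 0.178. Without the 10 sites with the most stops the shares were 15.7% ± 1.73, 23.1% ± 0.202 and 21.4% ± 0.859 at canonical sites, lower on day 7 than on day 3 in all samples. They were 52.5% ± 0.291, 56.2% ± 2.41 and 56.9% ± 0.85 in 3′ untranslated regions, and 3.09% ± 0.159, 3.33% ± 0.0213 and 2.93% ± 0.00531 on chromosome X. Of 16 classes, the samples of both days did not overlap in 8 for day 3 against day 0, 11 for day 7 against day 0 and 6 for day 7 against day 3. Chance gives 0.333 of classes, and the exact permutation p is 0.333 at its lowest. Camera placed canonical sites higher on day 3 than on day 0 (median 0.68, adjusted p = 8.33e-05, and adjusted p = 0.421 with an estimated correlation) and noncoding transcripts higher on day 7 than on day 0 (median 1.35, adjusted p = 0.0063, and adjusted p = 0.542 with an estimated correlation). From day 3 to day 7 noncoding transcripts were also higher (median 0.64, adjusted p = 0.00496, and adjusted p = 0.542 with an estimated correlation). On day 3 it placed lower than the rest, against day 0, potential G-triplex sites (median -1.04, adjusted p = 0.00699), potential G-quadruplex sites (-0.40, 0.0294), two-quartet sites (-0.28, 0.0483) and sites in coding sequence (-0.28, 0.0297). From day 0 to day 7 it placed lower sites in coding sequence (-0.37, 0.0063) and those in both 5′ untranslated region and coding sequence (-1.87, 0.0294). With an estimated correlation the adjusted p of these 6 was 0.421. By coverage, sites in 5′ untranslated regions were higher on day 7 than on day 0 (adjusted p = 0.0106) and than on day 3 (0.0202), with an adjusted p of 0.962 each with an estimated correlation.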

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

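The comparison of K+ with Li+ odds, the in vitro comparison of shares, and the tests of a single day 3 library, of the choice of sites, of stops of every kind and of the amount of RNA were chosen only after the results were seen. The threshold for the test with exchanged columns was set before its count was known, but the idea came from shares already seen.

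The K+ against Li+ odds differed between day 0 and day 3 in a test of the difference itself, at 42 of 847 sites. Pdap1 had a change of 3.44 ± 0.73 (log2, SE) and Prmt1 of 3.09 ± 0.56. The median K+ minus Li+ share was -0.575 ± 0.640 points on day 0 and 1.97 ± 1.33 points on day 3 (SD, n = 2), with -0.122 and -1.03 in the day 0 samples, the second of them doubted below, and 2.92 and 1.03 in the day 3 samples. That second difference was not tested beyond the exact permutation p of 0.333, the smallest possible.

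For this pattern, fewer reads in the day 3 libraries are argued against: with all columns thinned to the same reads per site, K+ lay above Li+ at 67.4% of sites on day 3 and 27.0% on day 0, a difference of 40.4 points, and at 45.7% on day 0 with the columns of replicate 2 exchanged. An exchange of the K+ and Li+ columns of day 0 replicate 2 is a possible explanation, since with the columns exchanged 0 sites passed (limma, 83 at an unadjusted p under 0.05, against 209 before) and the median change was 0.80 in place of 1.27 and the day 0 median log2 odds ratio 0.12 in place of -0.32, though it also widens the spread between the day 0 samples and 32 sites passed when that sample was left out. An effect of day 3 replicate 1 alone cannot be told apart from a change on day 3, because replicate 2 lay 16.9 points above the higher day 0 sample while replicates of 1 day differed by up to 28.3 points, and 0 sites passed without either day 3 replicate (23 and 216 at an unadjusted p under 0.05), with a median change of 0.71 without replicate 1 and of 1.53 without replicate 2. A lower Li+ share on day 3 stays open as part of it. At 847 sites the median Li+ share was 2.48% and 3.125% in the day 0 samples and 2.46% and 2.04% in the day 3 samples. The median K+ share was 2.36% and 1.96% against 5.41% and 3.03%, which argues against Li+ as the whole of the pattern. With the columns exchanged the Li+ median of day 0 replicate 2 was 1.96%, and the Li+ shares of the days overlapped. The K+ share itself had a median log2 odds change of 0.80 from day 0, and 0 of 954 sites passed in it. That change was 0.46 without day 3 replicate 1, 1.43 without replicate 2 and 0.57 with the columns exchanged. With the columns exchanged the median K+ share was 3.125% in day 0 replicate 2 and 3.03% in day 3 replicate 2, so the days overlapped. More folding of these motifs on day 3 stays open as a biological explanation and was not tested apart from these.

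The higher K+ stop share in vitro than in cells was a median log2 odds difference of 4.30. The choice of sites on the in vitro tables, in which every site had a higher stop share in K+ than in Li+, cannot be told apart from a difference between the preparations, because the 952 sites with 100 or more reads in all 4 tables, with a median of 4.07, had all passed the same choice. More stops of every kind in vitro cannot be told apart from it either: the Li+ difference was 0.86 against 4.20 in K+ at the sites covered in both, but the same choice by itself favours a larger gain in K+. Unfolding or DMS modification of the motifs in cells and a difference in the preparation of the in vitro RNA, which the labels do not describe, both stay open and may act together.

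For the K+ stop counts that changed between day 0 and day 7, a change in the amount of RNA is a candidate explanation at most sites. At the 53 changed sites K+ coverage moved in the direction of the stops at 52, by a median of 2.43 on the log2 scale against 2.98 for the stops, which includes sites listed at 0 on day 0. Since stops are part of the coverage, the shared direction is partly built in. At the 29 sites where the K+ share could be tested the medians were 1.49 and 2.32. The share moved in the direction of the stops at 10 of the 10 among them that rose and 12 of the 19 that fell. Its change in that direction exceeded that of the coverage at 11, 5 that rose and 6 that fell, but a choice of sites by their stops favours both. Part of the difference may be a change in folding, which stays open, and 0 sites passed in the K+ share (limma, 80 at an unadjusted p under 0.05, and 0 by the quasi-binomial test with 173).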

How the results depend on the processing

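The exchange of columns, the quasi-binomial tests, the removal of ribosomal and mitochondrial sites and the alternatives for coverage, for odds and for both replicates were chosen after the data were seen. Of the counts, 49 stayed within 1.5 times their value with a library left out and 33 moved, and 99 and 53 did so under other settings. Named sites kept their side of the threshold in 603 cases with a library left out and 1392 under other settings, lost it in 166 and 97, and gained it in 26 and 50. Single lists kept theirs in 321 and 252 cases, lost it in 9 and 24 and gained it in 12 and 3. For both, a change of direction was counted only where the main or the alternative value passed. Cases that kept their side without passing may have changed direction. Median odds changes differed from their main value by no more than a yardstick in 15 and 40 cases and by more in 7 and 7. The yardstick was the SD of the medians with a library left out, so for those cases staying within it is partly built in. The log2 K+ against Li+ odds ratio of Eif4a1 on day 3 was 2.82, turned to -0.063 (adjusted p = 0.993) without day 3 replicate 1 and was 3.23 without replicate 2, and the cause was not tested. The alternatives in DESeq2, and the main test in edgeR, were not run.

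For sites with changed K+ stops, median-ratio factors gave 0 for day 3 against day 0 (limma-voom, 48 at an unadjusted p under 0.05). Total stop counts gave 43 there and 93 for day 7 against day 0, and 4059 in vitro, because that scale keeps the overall gain. No filter gave 14, 154 and 134 for day 3 against day 0, day 7 against day 0 and day 7 against day 3, with more sites tested. At least 20 stops gave 1 for the first, 2 groups fitted alone 90 for the second, and stops summed per gene 6 for the first and 39 for the last. With libraries left out the counts ran from 0 to 3 for the first, from 21 to 69 for the second and from 14 to 22 for the last. For in vitro stops they ran from 308 to 1877. Leaving out a library also removes residual degrees of freedom, and beyond this and the constructions named the cause was not tested.

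A replicate block gave 0 changed sites for day 3 against day 0 (55 at an unadjusted p under 0.05). For K+ shares it gave 3, 24 and 2 by limma and 37, 138 and 7 by the quasi-binomial test. For coverage it gave 0 for day 3 against day 0 (189 at an unadjusted p under 0.05) and 290 for day 7 against day 0. The samples share only a number: deviations of replicates correlated by 0.25, -0.06 and 0.03 for coverage and 0.01, -0.17 and 0.09 for stops over the 3 pairs of days, so the numbers were not taken as pairs.

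For K+ shares, the quasi-binomial test without ribosomal and mitochondrial sites gave 2, 82 and 1, and limma gave 1 for day 7 against day 3 without day 3 replicate 2 and 0 without the others. For K+ against Li+ odds the quasi-binomial test gave 1, 7 and 34 on day 0, day 3 and day 7 and 4 for day 3 against day 0. Without ribosomal and mitochondrial sites it gave 81 on day 3, 60 on day 7, and 67, 28 and 4 between days. A coverage of 50 gave 26 on day 3, with fewer sites tested. With libraries left out the counts ran from 0 to 1 on day 0, fell from 42 to 0 on day 3 without either day 3 replicate, and ran from 0 to 70 for day 3 against day 0 and from 0 to 22 for day 7 against day 0. With exchanged columns 1 site changed in stops for day 3 against day 0, and the odds gave 3 on day 7 and 0 for day 3 against day 0, and without ribosomal and mitochondrial sites 7 and 0. The cause was not tested except for the exchange.

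In vitro shares at a coverage of 100 gave 944 of 952 sites. Coverage per gene gave 25 with K+ libraries alone and 1 with Li+ alone for day 3 against day 0, and 172 with Li+ alone for day 7 against day 3. Genes listed above 0 in all samples gave 5, 125 and 76, with fewer genes tested. With libraries left out the counts ran from 0 to 331, from 113 to 1064 and from 0 to 585. The cause was not tested. Lists fell from 12, 9 and 1 calls to 0, 0 and 0 with an estimated correlation, also where it lay below the preset 0.01 (-0.032 for stress genes on day 3). That form of the test has fewer degrees of freedom, so the losses do not measure correlation among sites alone. How much each contributed was not tested. Site classes by the mean log2 CPM gave 1 for day 3 against day 0 and 16 for day 7 against day 0 and against day 3, all 16 up in each. That mean weighs every site alike and need not sum to a fixed total. The K+ libraries listed 2989 and 1974 sites at 0 on day 3 and 168 and 515 on day 7, and an effect of this was not tested. A higher stop share in K+ than in Li+ in both replicates held at 3 sites on day 3 and 1 on day 7 without ribosomal and mitochondrial sites, and at 1453 in vitro at a coverage of 50. In single replicates the counts ran from 3 to 6 on day 0, 7 to 168 on day 3 and 6 to 214 on day 7. Outside ribosomal and mitochondrial RNA day 0 replicate 2 held 7581 K+ stops and day 3 replicate 1 8414, and an effect of depth on these counts was not tested.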
